A study of Homo sapiens with 23 samples.

How the data were processed

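RNA from SCP21, a subline of the human breast cancer cell line MDA-MB-231, was measured by paired-end RNA-seq on an Illumina NovaSeq in 23 libraries. Per the labels' protocols, cells carrying a red fluorescent protein were placed in the mammary fat pad, the lung or the bone of nude mice, sorted from the lesions after 4 weeks, and cultured again with a passage every 5 days. One library was made from the parental cells that had not been in a mouse. The labels give 3 libraries of mammary fat pad cells (MFP P3) and 3 of lung cells (lung P3), each at passage 3, and 4 libraries of bone cells at each of passage 3 (bone P3), passage 6 (bone P6) and passage 9 (bone P9). A further 4 libraries came from bone cells at passage 3 that received 1 µM of the EZH2 inhibitor EPZ011989 for 5 days (bone P3 EPZ). Each replicate number of the bone groups names the same mouse, so the 16 bone libraries come from 4 mice.

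The deposited values are FPKM, fragment counts scaled to gene length and library total, in 1 table that also gives gene identifiers, symbols, positions and lengths per the file headers. Per the submitters' processing notes, CASAVA and the aligner STAR 2.5 were used; the counting tool, its strand setting and the genome build are not given in the sources used here. All 58676 gene identifiers are in the GRCh38 annotation used for GC content, and 95.3% have the same start and end there, so positions are printed as the file gives them. Multiplying FPKM by length gave whole numbers of fragments for 100% of the values above 0 (tolerance 0.02), with totals between 17817682 and 24983825 fragments per library. At the lowest depth, 1 fragment on a gene of 1 kb is 0.0561 FPKM. No pair of replicates differed by as little as sampling noise: the chi-square per degree of freedom lay between 8.51 and 56.5 over 30 pairs.

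Genes with at least 1 FPKM in at least 3 of the 22 replicated libraries were tested, which left 13182 genes, of which 10428 were protein-coding. Values were analysed as log2(FPKM + 1), so that log2 changes are on that scale and understate the change of genes with low values. One limma-trend model (limma 3.58.1 in R 4.3.3) with group as its only term was fitted to the 22 libraries, which share 1 estimate of the spread. Bone libraries of the same mouse count as independent in it, also for the spread behind the site comparisons. The MFP P3 libraries, whose replicates differed most, get that same spread. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, and every adjusted p of a single gene comes from this model unless another is named. The parental line has 1 library and no test; its gene lists were set against 10000 random lists of the same size matched on mean expression.

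Of 35 gene lists written before the data were examined, 28 had at least 5 tested genes. Member counts below are of tested genes only. Tested were 15 of 33 genes described as repressed by EZH2, 6 of 11 of the MHC class II pathway, 14 of 28 epithelial and 13 of 23 stemness genes. The filter counts libraries of all groups, so a member can enter through the group where it is high. The 28 lists were tested with camera of limma at a preset correlation of 0.01 between genes, adjusted over the lists of each comparison, and again with the correlation estimated from the data. With the estimated correlation 2 of 60 list calls held, both of the list of feedback and early targets of ERK signalling, in inhibitor-treated cells against bone P3 and against bone P6. The latter was lost with that correlation after a GC trend was removed (camera adjusted p = 0.0502). All other list calls in the report are therefore given with the p of that second test. Named genes are, per comparison, the 12 with the largest rise and the 12 with the largest fall among genes that passed, were protein-coding, reached a mean of 2 FPKM in one of the groups and did not overlap between the groups' libraries; the subunits of the Polycomb complex PRC2; and up to 4 members that passed from each list. For the parental line they are the 10 highest and the 10 lowest genes outside the range of the 10 passage 3 libraries.

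Libraries of the same mouse were paired by the labels. Their deviations from the group means correlated across genes with a mean r of 0.189 (range -0.0445 to 0.435, 24 pairs). For libraries of different mice it was -0.0630 (72 pairs), which is no separate finding, since deviations within a group cancel out. Pairs of mouse 320 lay between 0.323 and 0.435, and no other pair of the same mouse was above 0.233. Results among bone groups are therefore also given with the mouse as a block where the block changed a call or moved a count by over 1.5 times. In the site comparisons a replicate number names different mice.

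Each count was recomputed with a pseudocount of 0.1, without the filter, with median-ratio scaling, after rescaling to TPM, with quantile normalization, with the compared groups alone, with the replicate number as a block, and without each library in turn. Quantile normalization gives every library the same set of values. It can therefore hide a change shared by genes with very high values, such as those encoded in mitochondria. Added after the data were examined were corrections for trends with GC content or gene length, in 2 forms that kept or removed the library's overall level and together with median-ratio scaling, voom on the recovered fragments, and fits without mouse 320, whose libraries lay apart on the second principal component. The model was tested on simulated data with known changes in 200 genes and in a further gene list raised 1.5-fold. These genes were drawn from those with a mean of at least 2 FPKM, so the shares recovered do not cover tested genes with lower values. For bone P3 against MFP P3 it recovered 44.8% of changes of 1.5-fold, 85.1% of 2-fold and 95.5% of 4-fold changes; for inhibitor-treated against untreated bone P3 cells the shares were 49.3%, 91.0% and 100%. Among the calls 3.64% to 9.29% were false. The simulated libraries had no mouse effect, no correlation between genes and no GC or level trend, so the false share of the real calls may differ. Single values across libraries were compared with two-sided exact permutation tests; among bone groups the differences within mice were used, a test added after the data were examined, which with 4 mice cannot go below 0.125. These were run in Python 3.11.15.

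Covariances of 2 changes that use the same control libraries were computed with different mice on each side (6 ways of splitting the 4 mice), so that no library was shared. Without strand information, reads of overlapping genes cannot be told apart; this concerns KRT86 (with KRT81 and KRT7), S100A4 (with S100A3), S100A6, SPINK4, HK2, LAMA5, COL5A1, VIM, TGFB1, CCND1, HMGA1, DHCR7, DLC1, RUNX2 and FOXM1, whose values are uncertain by that much. Values of HLA genes, of SPANXB1, of histone and ribosomal protein genes and of other genes with near-identical copies depend on how such reads were assigned.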

Results

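Gene expression was compared between SCP21 breast cancer cells that had grown in the mammary fat pad, the lung or the bone of mice and were then cultured again. Bone cells were sampled at passages 3, 6 and 9, and at passage 3 also with an inhibitor of the histone methyltransferase EZH2. The 23 libraries held between 17817682 and 24983825 fragments. Among human markers of other cell types, 9 of 12 bone cell genes, 13 of 16 stromal genes and 16 of 17 blood cell genes stayed under 1 FPKM in every library. The highest were RUNX2, which tumour cells can also express (9.59 FPKM), and CSF1R (5.06 FPKM). The hosts were mice and the genes in the table are human, so these values say little about host cells.

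**Figure D1:**
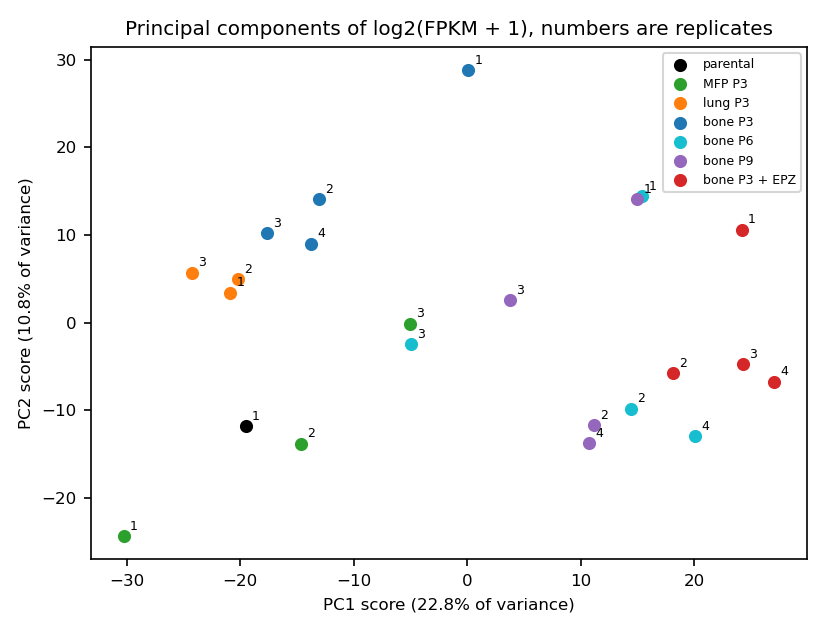
Scores of the 23 libraries on the first (x axis, 22.8% of variance) and second (y axis, 10.8%) principal components of log2(FPKM + 1). Each point is 1 library, coloured by group. Inhibitor-treated libraries have the highest mean score on the first component, and bone P3 replicate 1 has the highest score of any library on the second.

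Cells from bone were set against cells from fat pad tumours at passage 3, to ask what growth in bone left behind. CDK15, a cyclin-dependent kinase gene (ENSG00000138395, chromosome 2, 201790461 to 201895550), stood at 15.7 ± 3.36 FPKM (SD, n = 4) in bone cells and 3.22 ± 1.84 (n = 3) in fat pad cells, a log2 difference of 2.06 ± 0.28 (SE, limma adjusted p = 0.000922). FPR1, the receptor for formylated peptides (ENSG00000171051, chromosome 19, 51745172 to 51804110), stood at 16.7 ± 8.49 against 4.40 ± 0.541 FPKM (limma adjusted p = 0.00455). The calcium-binding S100A6 reached 3714 ± 843 against 1505 ± 516 FPKM, and S100A2 was higher by 1.54 ± 0.33 on the log2 scale. ID3, an inhibitor of basic helix-loop-helix factors, was higher by 1.15 ± 0.27 (limma adjusted p = 0.0295), and ABCG2, a drug efflux transporter, by 0.92 ± 0.24 (limma adjusted p = 0.0424). The adipogenic receptor gene PPARG stood at 18.7 ± 3.72 against 10.6 ± 1.21 FPKM, and the interferon-induced BST2 at 98.9 ± 5.80 against 54.5 ± 22.6.

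Lower in bone cells was IGFBP3, which binds insulin-like growth factors (3.87 ± 0.553 against 9.78 ± 1.66 FPKM, log2 -1.14 ± 0.13, limma adjusted p = 0.000156). The hypoxia-induced NDRG1 stood at 10.6 ± 2.46 against 26.8 ± 3.74 FPKM. The tight junction gene CLDN1 (log2 -1.42 ± 0.27), the transcription factor KLF5 (-1.28 ± 0.22), the RNA-binding CELF2 (-1.62 ± 0.25) and ENPP4 (-1.67 ± 0.21) were also lower. Of 18 hypoxia genes 0 were higher, 2 lower and 16 did not pass (0 and 8 adjusted over the list alone, median log2 -0.34, camera adjusted p = 0.000133, or 0.45 with an estimated correlation); the lower genes are NDRG1 and ENO2. Of 14 glycolysis genes 0 were higher, 3 lower and 11 did not pass (0 and 3 adjusted over the list alone, median log2 -0.24, camera adjusted p = 0.0018, or 0.45 with an estimated correlation), the lower ones being HK2 (log2 -0.87 ± 0.22), ENO2 (-0.55 ± 0.15) and PFKP (-0.47 ± 0.11). Of 21 inflammatory genes 0 were higher, 1 lower and 20 did not pass (0 and 7 adjusted over the list alone, median log2 -0.43, camera adjusted p = 0.000241, or 0.45 with an estimated correlation), TNFAIP3 being the lower one. Of 20 cholesterol synthesis genes 0 were higher, 1 lower and 19 did not pass (1 and 8 adjusted over the list alone, median log2 -0.47, camera adjusted p = 0.000241, or 0.672 with an estimated correlation), the lower one being SQLE. Of 34 ribosomal protein genes 1 was higher, 0 lower and 33 did not pass (4 and 0 adjusted over the list alone, median log2 0.29, camera adjusted p = 8.83e-12, or 0.45 with an estimated correlation), the higher one being RPS14.

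EZH2 itself (ENSG00000106462, chromosome 7) stood at 25.9 ± 2.04 FPKM in bone cells and 25.8 ± 0.757 in fat pad cells (log2 0.00 ± 0.10, limma adjusted p = 0.991). Its PRC2 partner JARID2 was lower by -0.39 ± 0.09 on the log2 scale, the only one of 11 PRC2 genes to pass. In all 385 genes passed, 190 higher and 195 lower in bone cells, 48 of them by at least 1 in log2(FPKM + 1). With median-ratio scaling 498 passed (359 higher and 139 lower). With quantile normalization 231 were higher and 134 lower, and after rescaling to TPM 78 and 124. The count was 66, 150 and 1048 without MFP P3 replicates 1, 2 and 3. It was 171 and 132 without bone P3 replicates 1 and 2, and 3 with the spread taken from these 2 groups alone. Of the 36 named genes that passed here, 23 lost the call when 1 or another library was left out. All 36 lost it with the replicate number as a block, which here groups different mice.

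Cells from lung lesions differed from fat pad cells in fewer genes. NDRG1 was again lower (9.30 ± 2.71 against 26.8 ± 3.74 FPKM, n = 3 and 3, log2 -1.46 ± 0.25, limma adjusted p = 0.0238). The matrix genes COL5A1 (log2 -1.30 ± 0.24) and LAMA5 (-1.32 ± 0.28), the secreted STC1 (-0.93 ± 0.18), the exporter ABCC3 (-1.14 ± 0.22) and the growth factor binding protein IGFBP4 (109 ± 22.4 against 217 ± 44.7 FPKM) were lower. Higher were NDUFS4, a subunit of respiratory complex I (62.0 ± 4.60 against 38.5 ± 3.27 FPKM, limma adjusted p = 0.0196), and the citrate cycle enzyme FH (70.7 ± 2.38 against 50.7 ± 4.70 FPKM). Of 18 hypoxia genes 0 were higher, 1 lower and 17 did not pass (0 and 9 adjusted over the list alone, median log2 -0.43, camera adjusted p = 4.2e-06, or 0.517 with an estimated correlation), NDRG1 being the lower one. Of 14 glycolysis genes 0 were higher, 0 lower and 14 did not pass (0 and 6 adjusted over the list alone, median log2 -0.28, camera adjusted p = 0.000323, or 0.517 with an estimated correlation). Of 13 genes encoded in mitochondria 0 were higher, 0 lower and 13 did not pass (0 and 0 adjusted over the list alone, median log2 0.12, camera adjusted p = 0.00893, or 0.783 with an estimated correlation). With quantile normalization, which can hide such a difference, the set did not pass (camera adjusted p = 0.995). EZH2 differed by 0.02 ± 0.11 (limma adjusted p = 0.962).

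Of the 50 genes that passed between lung and fat pad cells, 12 were higher and 38 lower in lung cells. With median-ratio scaling the numbers were 56 and 36. They were, with quantile normalization, 19 and 19, and after rescaling to TPM 2 and 34. Without MFP P3 replicates 1, 2 and 3 the count was 8, 2 and 321. Without lung P3 replicates 1, 2 and 3 it was 18, 3 and 6, and the 2 groups alone gave 1. All 23 named genes that passed here lost the call when 1 or another library was left out. NDRG1 was lower than in fat pad cells in both bone and lung cells. Both differences use the same 3 fat pad libraries, which could not be halved, so part of their likeness may come from sharing. Their covariance was 0.0543, where simulations with no effect and the same sharing gave 0.0269. Their correlation r was 0.593, against 0.522 in those simulations. The simulations drew deviations from all 22 libraries, and the replicates that differed most were of MFP P3, so sharing may give more than this.

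**Figure D2:**
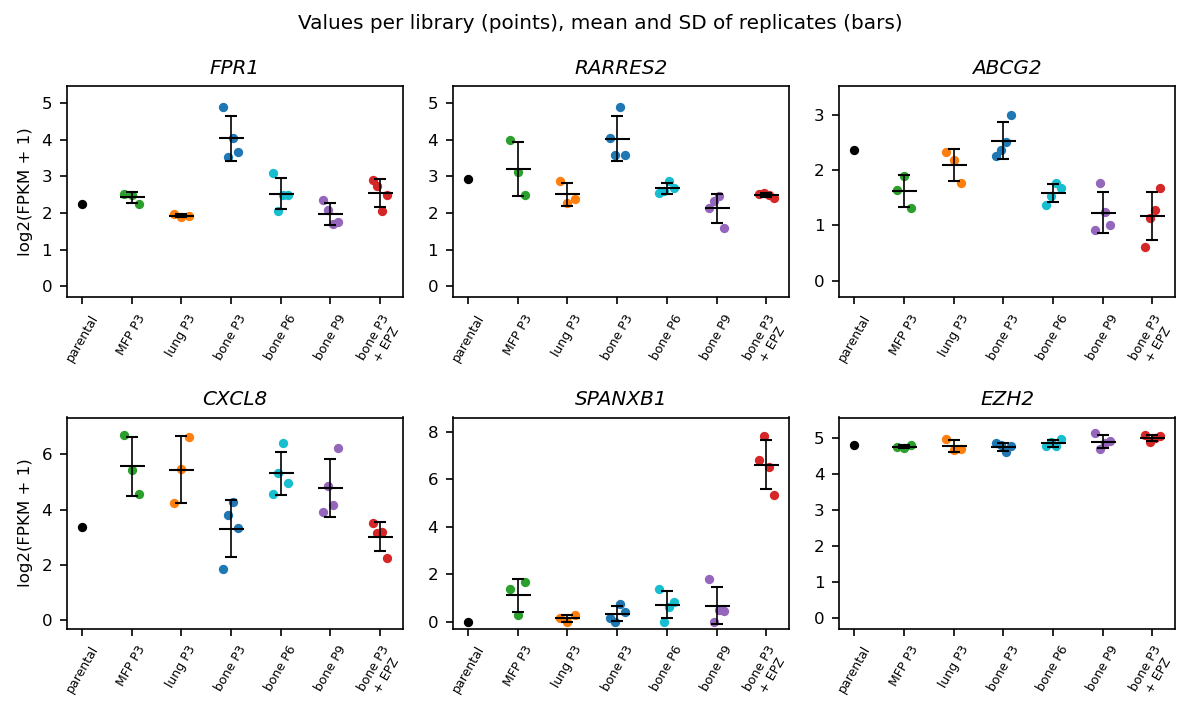
Values of 6 genes as log2(FPKM + 1) (y axis) by group (x axis). Each point is 1 library, and bars give the mean and SD of replicated groups. FPR1, RARRES2 and ABCG2 have lower means in bone P6, bone P9 and inhibitor-treated libraries than in bone P3, and SPANXB1 is high in the inhibitor-treated libraries alone.

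The direct comparison of bone with lung cells tests whether the sites differ from each other. FPR1 (16.7 ± 8.49 against 2.82 ± 0.0993 FPKM, n = 4 and 3, log2 2.11 ± 0.27, limma adjusted p = 0.00147) and CDK15 (log2 2.06 ± 0.28, limma adjusted p = 0.00216) were higher in bone cells. RARRES2, which encodes the chemoattractant chemerin, was higher by 1.52 ± 0.30, the phosphodiesterase PDE4D by 0.74 ± 0.14 and the antioxidant GPX3 by 0.51 ± 0.09 on the log2 scale. IGFBP3 was lower in bone cells (3.87 ± 0.553 against 9.00 ± 0.825 FPKM, limma adjusted p = 0.00147), as were KCTD12 (log2 -1.23 ± 0.22), CELF2 (-1.32 ± 0.25) and the membrane protein STOM (-0.97 ± 0.19). Of 20 cholesterol synthesis genes 0 were higher, 0 lower and 20 did not pass (1 and 4 adjusted over the list alone, median log2 -0.52, camera adjusted p = 3.34e-09, or 0.527 with an estimated correlation). Of 19 targets of the stress factor ATF4 0 were higher, 0 lower and 19 did not pass (0 and 5 adjusted over the list alone, median log2 -0.44, camera adjusted p = 4.1e-08, or 0.486 with an estimated correlation). Of 13 collagen genes 0 were higher, 0 lower and 13 did not pass (5 and 1 adjusted over the list alone, median log2 0.62, camera adjusted p = 0.000361, or 0.545 with an estimated correlation). Of 12 genes described for lung-tropic sublines of this cell line 0 were higher, 0 lower and 12 did not pass (5 and 0 adjusted over the list alone, median log2 0.63, camera adjusted p = 0.000361, or 0.0616 with an estimated correlation). In all 20 genes passed, 9 higher and 11 lower, or 12 and 5 after rescaling to TPM. The count was 3 and 7 without lung P3 replicates 2 and 3 and 4 and 10 without bone P3 replicates 1 and 3. The limma model of the 2 groups alone gave 0, where 1303 genes had an unadjusted p under the threshold. Of 15 named genes that passed, 12 lost the call when 1 or another library was left out. All 15 lost it with the replicate number as a block, which here groups different mice. EZH2 differed by -0.01 ± 0.10 (limma adjusted p = 0.981).

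Bone cells were followed from passage 3 to passage 6 to see what changed in culture. FPR1 fell from 16.7 ± 8.49 to 4.98 ± 1.87 FPKM (n = 4 and 4, log2 -1.51 ± 0.25, limma adjusted p = 0.00182), RARRES2 from 16.6 ± 8.46 to 5.43 ± 0.686, ID3 from 4.97 ± 1.24 to 1.65 ± 0.777 and ABCG2 from 4.90 ± 1.45 to 2.01 ± 0.341. The transcription factor MYC rose from 25.5 ± 3.27 to 56.1 ± 9.62 FPKM (log2 1.10 ± 0.17, limma adjusted p = 0.00118), and the intermediate filament gene VIM from 103 ± 10.8 to 178 ± 24.7. The chemokine CXCL8 rose from 10.7 ± 6.58 to 43.6 ± 26.8 FPKM. Of lipid synthesis genes, the fatty acid synthase FASN rose from 7.20 ± 1.72 to 21.5 ± 5.71 FPKM, and the desaturase SCD by 1.33 ± 0.41 (limma adjusted p = 0.0413, or 0.0564 with the mouse as a block).

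Of 20 cholesterol synthesis genes 8 rose, 0 fell and 12 did not pass (11 and 0 adjusted over the list alone, median log2 0.45, camera adjusted p = 0.000532, or 0.38 with an estimated correlation), among them SREBF2 (log2 1.09 ± 0.22) and DHCR7 (1.28 ± 0.32). Of 14 glycolysis genes 6 rose, 0 fell and 8 did not pass (7 and 0 adjusted over the list alone, median log2 0.20, camera adjusted p = 0.00265, or 0.364 with an estimated correlation), among them HK2 (4.52 ± 1.47 to 11.1 ± 2.30 FPKM) and PFKP (log2 0.74 ± 0.10). Of 20 early targets and feedback genes of ERK 8 rose, 0 fell and 12 did not pass (12 and 0 adjusted over the list alone, median log2 0.52, camera adjusted p = 0.000115, or 0.174 with an estimated correlation), among them MYC and FOSL1 (log2 0.83 ± 0.18). Of 15 genes described as repressed by EZH2 5 rose, 0 fell and 10 did not pass (6 and 0 adjusted over the list alone, median log2 0.55, camera adjusted p = 0.00265, or 0.205 with an estimated correlation), among them TIMP2 (18.4 ± 3.00 to 37.3 ± 8.54 FPKM) and IGFBP3 (log2 0.65 ± 0.12). Of 19 ATF4 targets 5 rose, 0 fell and 14 did not pass (7 and 0 adjusted over the list alone, median log2 0.37, camera adjusted p = 0.00265, or 0.38 with an estimated correlation), among them TRIB3 and CEBPB. Of 13 genes encoded in mitochondria 0 rose, 3 fell and 10 did not pass (0 and 6 adjusted over the list alone, median log2 -0.27, camera adjusted p = 9.2e-06, or 0.364 with an estimated correlation). With quantile normalization, which can hide such a change, the set leaned to higher values (camera adjusted p = 0.559). All genes with symbols starting with MT-, a wider set than this list, took 17.9% of fragments at passage 3 and 14.4% at passage 6. The share was lower in each of the 4 mice (exact permutation p = 0.125 within mice, the smallest possible).

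Between passages 3 and 6, 1428 genes passed, 1259 rising and 169 falling, 40 of them by at least 1 in log2(FPKM + 1). With the mouse as a block it was 2569 (2057 and 512). With median-ratio scaling 813 rose and 401 fell, with quantile normalization 763 and 440. The count was 912 without bone P3 replicate 3, and 724 and 554 without bone P6 replicates 2 and 4. It was 792 without the filter and 278 with the 2 groups alone. EZH2 differed by 0.09 ± 0.09 (limma adjusted p = 0.616), while JARID2 rose by 0.50 ± 0.09.

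At passage 9 several genes that had been higher in bone cells were lower than at passage 3. FPR1 stood at 3.00 ± 0.873 FPKM (n = 4 and 4, log2 -2.06 ± 0.25, limma adjusted p = 0.000189) and RARRES2 at 3.47 ± 1.09 (log2 -1.91 ± 0.28). S100A6 fell from 3714 ± 843 to 1188 ± 394 FPKM, S100A4 from 1461 ± 325 to 557 ± 150 and ABCG2 from 4.90 ± 1.45 to 1.41 ± 0.676. IGFBP3 rose to 7.81 ± 0.711 FPKM (log2 0.86 ± 0.12, limma adjusted p = 0.000376), against 9.78 ± 1.66 in fat pad cells. The cytokine CSF2 rose by 1.39 ± 0.40, the inflammatory IL32 by 1.14 ± 0.30, the homeobox gene HOXB9 by 1.10 ± 0.22 and the polyamine enzyme SRM by 1.15 ± 0.23 on the log2 scale.

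Of 21 inflammatory genes 7 rose, 0 fell and 14 did not pass (8 and 0 adjusted over the list alone, median log2 0.42, camera adjusted p = 0.00287, or 0.499 with an estimated correlation), among them CSF2 and NFKB1 (log2 0.70 ± 0.10). Of 32 cell cycle genes 9 rose, 1 fell and 22 did not pass (15 and 2 adjusted over the list alone, median log2 0.27, camera adjusted p = 0.0476, or 0.659 with an estimated correlation), among them the replication licensing factor CDT1 (3.87 ± 1.06 to 8.37 ± 0.404 FPKM), FOXM1 and the kinase PLK1 (log2 0.72 ± 0.14). This set was at camera adjusted p = 0.0512 with the mouse as a block and 0.053 with median-ratio scaling. Of 15 genes described as repressed by EZH2 5 rose, 0 fell and 10 did not pass (6 and 1 adjusted over the list alone, median log2 0.50, camera adjusted p = 0.0476, or 0.499 with an estimated correlation), among them IGFBP3 and DLC1 (log2 0.52 ± 0.07). This call was lost after a GC trend was removed (camera adjusted p = 0.0849, or 0.0525 with the block), a test chosen after the data were seen, and with quantile normalization. Of 14 glycolysis genes 6 rose, 0 fell and 8 did not pass (6 and 1 adjusted over the list alone, median log2 0.10, camera adjusted p = 0.0261, or 0.499 with an estimated correlation), led by HK2 (log2 0.99 ± 0.20), with camera adjusted p = 0.0593 under the block and 0.0865 after a GC trend was removed. Of 13 genes encoded in mitochondria 0 rose, 1 fell and 12 did not pass (1 and 5 adjusted over the list alone, median log2 -0.23, camera adjusted p = 0.006, or 0.611 with an estimated correlation). The set leaned to higher values with quantile normalization, which can hide such a change (camera adjusted p = 0.295).

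In all 1938 genes passed between passages 3 and 9, 1383 rising and 555 falling, 66 of them by at least 1 in log2(FPKM + 1). With the mouse as a block it was 3180 (2093 and 1087). Rescaling to TPM gave 2183 and 244, and quantile normalization 1209 and 812. The count was 1283 without bone P9 replicate 2, 1191 without the filter and 1241 with the 2 groups alone. FPR1, RARRES2 and ABCG2 fell at both passages. With different mice on each side the covariance of the passage 6 and passage 9 changes was 0.0533 ± 0.00492 (SD over 6 splits), where simulations with no effect, split in the same way, gave -0.0241 to 0.0221.

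FPR1, S100A6 and ABCG2 were higher in bone P3 than in fat pad cells and fell by passage 9, while IGFBP3 and HK2 were lower and rose. Both comparisons use the bone P3 libraries, which favours opposite changes. With different mice on each side their covariance was -0.0163 ± 0.0123 (SD over 6 splits, range -0.0332 to 0.00361). Simulations with no effect, split in the same way, gave -0.0233 to 0.0203, a range that holds the observed value. Unsplit it was -0.0365, and -0.0222 from shared libraries alone. For passage 6 the split covariance was -0.0190 ± 0.00315, below 0 in all 6 splits, also inside its simulated range (-0.0298 to 0.0262). With no library shared, opposite changes are therefore not told apart from no effect in these simulations. The unsplit value includes the effect of sharing.

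Bone cells treated with EPZ011989, which blocks the methyltransferase activity of EZH2, were compared with untreated bone P3 cells. SPANXB1, a cancer-testis gene (ENSG00000227234, chromosome X, 141002591 to 141003706), rose from 0.282 ± 0.296 to 116 ± 77.4 FPKM (n = 4 and 4, log2 6.28 ± 0.43, limma adjusted p = 6.31e-08). The pioneer factor FOXA2 rose from 0.135 ± 0.122 to 3.15 ± 1.49 FPKM (limma adjusted p = 0.00124), the chromatin protein HMGA1 from 295 ± 111 to 959 ± 157 and KLF5 from 2.09 ± 0.999 to 7.21 ± 1.16. ABCG2 (ENSG00000118777) fell from 4.90 ± 1.45 to 1.33 ± 0.679 FPKM (log2 -1.36 ± 0.22, limma adjusted p = 0.000191), RARRES2 to 4.61 ± 0.218, FPR1 to 4.98 ± 1.45, and the protease HTRA1 by -1.20 ± 0.27 on the log2 scale. The transcript of the target, EZH2, stood at 30.8 ± 1.81 against 25.9 ± 2.04 FPKM (limma adjusted p = 0.0726, or 0.0421 with the mouse as a block), and an activity inhibitor need not change it. Of 11 PRC2 genes 3 rose, 0 fell and 8 did not pass (4 and 0 adjusted over the list alone, median log2 0.16, camera adjusted p = 0.387, or 0.641 with an estimated correlation), the rises being PHF19 (log2 0.72 ± 0.13), JARID2 (0.42 ± 0.09) and AEBP2 (0.39 ± 0.10).

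Of 20 early targets and feedback genes of ERK 16 rose, 0 fell and 4 did not pass (18 and 0 adjusted over the list alone, median log2 0.81, camera adjusted p = 8.02e-09, or 0.0132 with an estimated correlation). They include FOSL1 (85.1 ± 16.7 to 218 ± 40.6 FPKM, limma adjusted p = 4.89e-05), EGR1 (log2 1.29 ± 0.32) and the ephrin receptor EPHA2 (20.2 ± 4.77 to 43.2 ± 4.78 FPKM). Of 33 genes described as repressed by EZH2 15 passed the filter and were tested. Of these 15, 7 rose, 0 fell and 8 did not pass (7 and 0 adjusted over the list alone, median log2 0.51, camera adjusted p = 0.0163, or 0.276 with an estimated correlation), the rises including TIMP2 (18.4 ± 3.00 to 45.8 ± 4.28 FPKM), KLF2 (log2 1.25 ± 0.29) and TIMP3 (1.04 ± 0.29). This set was at camera adjusted p = 0.0587 after a GC trend was removed, or 0.0128 with the block, a test chosen after the data were seen. Of 19 targets of the co-activator YAP 9 rose, 0 fell and 10 did not pass (11 and 0 adjusted over the list alone, median log2 0.41, camera adjusted p = 0.00175, or 0.515 with an estimated correlation), among them CTGF (log2 1.04 ± 0.21). Of 6 MHC class II pathway genes 3 rose, 0 fell and 3 did not pass (4 and 0 adjusted over the list alone, median log2 1.02, camera adjusted p = 0.0658, or 0.567 with an estimated correlation), among them CD74 (23.3 ± 6.48 to 47.3 ± 11.6 FPKM), and with the mouse as a block the set passed (camera adjusted p = 0.00671). Of 13 genes encoded in mitochondria 0 rose, 12 fell and 1 did not pass (0 and 12 adjusted over the list alone, median log2 -0.52, camera adjusted p = 2.12e-11, or 0.148 with an estimated correlation), among them MT-ND5 (1665 ± 374 to 915 ± 63.1 FPKM). The set call was lost with quantile normalization (camera adjusted p = 0.6), which can hide a change shared by genes with such high values. The share of fragments in all genes with symbols starting with MT- was 12.2% against 17.9%, again lower in each of the 4 mice (exact permutation p = 0.125 within mice, the smallest possible).

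In all 2799 genes passed, 2502 rising and 297 falling under the inhibitor, 177 of them by at least 1 in log2(FPKM + 1). With median-ratio scaling 1731 rose and 915 fell, with quantile normalization 1579 and 1172, and after rescaling to TPM 4089 and 71, so the balance depends on the scaling. The labels do not say whether untreated cells were held for the same 5 days or given a vehicle.

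**Figure D3:**
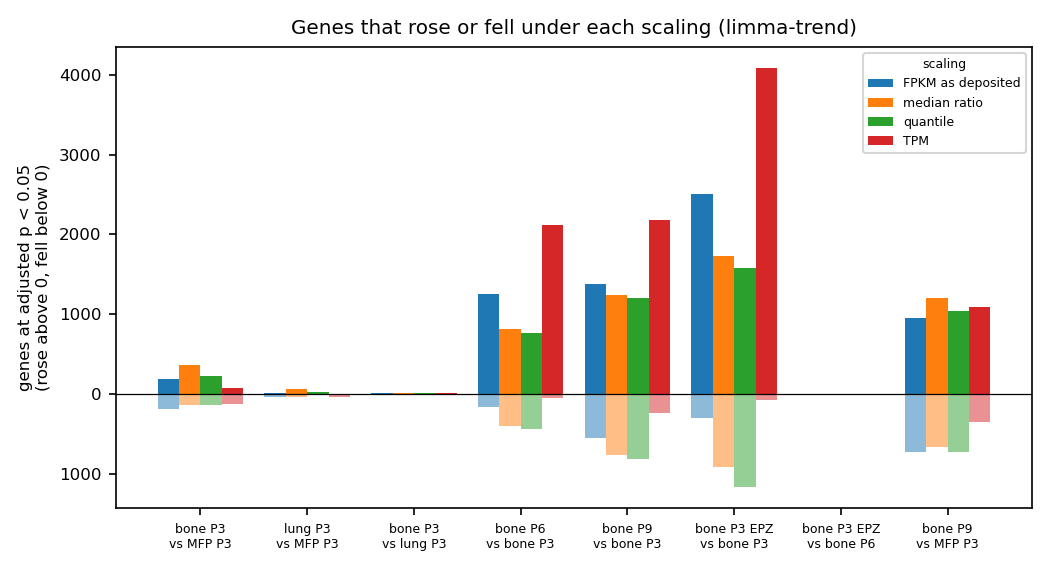
Number of genes at limma adjusted p under 0.05 (y axis) that rose (above 0) or fell (below 0) in each comparison (x axis), with FPKM as deposited and with 3 other scalings (colours). For inhibitor-treated against untreated bone P3 cells, rises and falls number 2502 and 297 as deposited and 1579 and 1172 with quantile normalization.

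Changes under the inhibitor were set against changes over passages. FOSL1 and TIMP2 rose, and FPR1 fell, in both. With different mice on each side the covariance of the passage 6 and inhibitor changes was 0.0586 ± 0.0134 (SD over 6 splits), where simulations with no effect gave -0.0231 to 0.0304. The covariance of the passage 9 and inhibitor changes was 0.0609 ± 0.00993 (SD over 6 splits). Simulations with no effect, split in the same way, gave -0.0184 to 0.0294. Unsplit it was 0.0815, and 0.0231 from shared libraries alone.

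Inhibitor-treated cells were also compared directly with passage 6 cells, in which bone P3 takes no part. All 5 genes that passed were higher under the inhibitor: SPANXB1 (116 ± 77.4 against 0.728 ± 0.676 FPKM, n = 4 and 4, limma adjusted p = 1.93e-07), the nucleosome-binding HMGN5 (3.66 ± 0.932 against 0.612 ± 0.420), ENPP4 (2.36 ± 0.181 against 0.481 ± 0.204), IGFBP4 (433 ± 15.3 against 211 ± 30.1) and LCP1 (log2 1.21 ± 0.20, limma adjusted p = 0.0191). LCP1, which bundles actin, lies outside the rule for named genes and was named after its values were seen. Of 20 early targets and feedback genes of ERK 0 were higher, 0 lower and 20 did not pass (8 and 0 adjusted over the list alone, median log2 0.35, camera adjusted p = 3.3e-07, or 0.0363 with an estimated correlation). With the estimated correlation this call was lost after a GC trend was removed (camera adjusted p = 0.0502), a test chosen after the data were seen. Of 6 MHC class II pathway genes 0 were higher, 0 lower and 6 did not pass (6 and 0 adjusted over the list alone, median log2 0.85, camera adjusted p = 7.5e-07, or 0.218 with an estimated correlation). Of 20 cholesterol synthesis genes 0 were higher, 0 lower and 20 did not pass (0 and 0 adjusted over the list alone, median log2 -0.27, camera adjusted p = 2.72e-07, or 0.429 with an estimated correlation). The gene count was 2, 1 and 3 without bone P6 replicates 2, 3 and 4, and 1 and 1 without inhibitor replicates 2 and 3. With the mouse as a block it was 35 (33 higher and 2 lower).

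**Figure D4:**
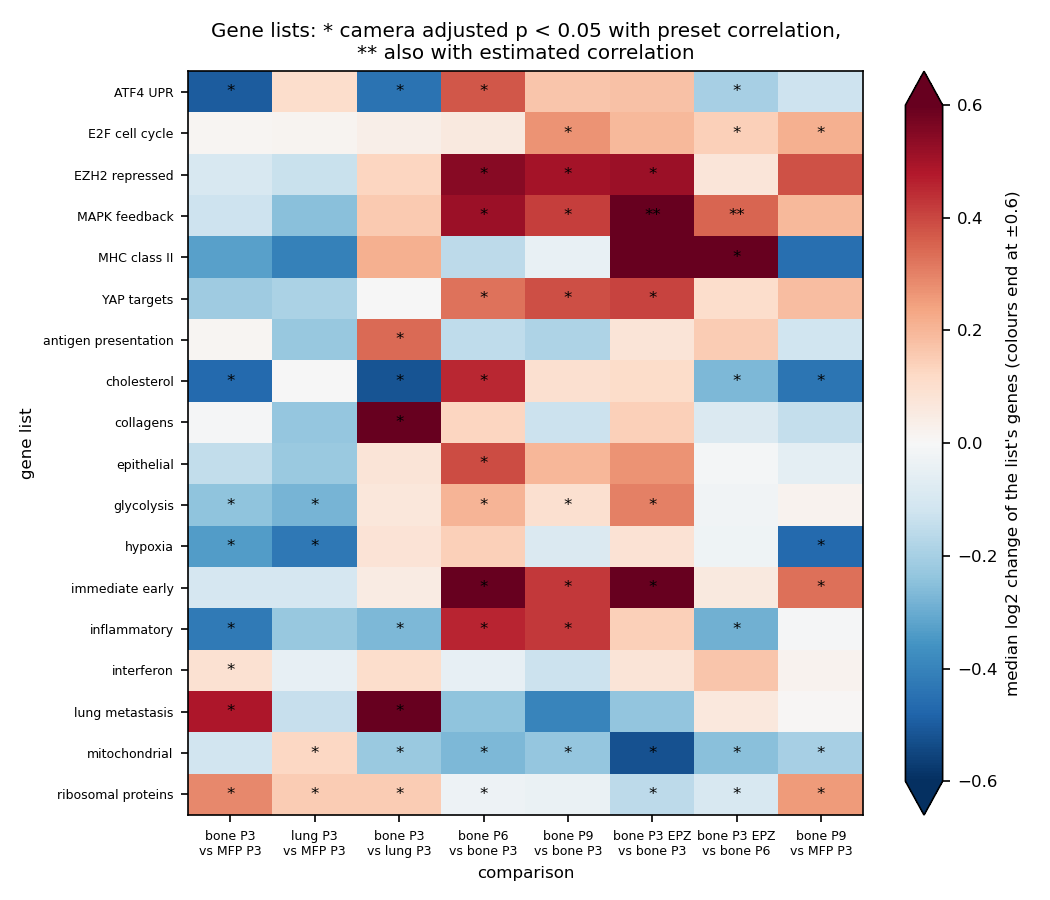
Median log2 change (colour) of gene lists that passed in at least 1 comparison (y axis) across the 8 comparisons (x axis). An asterisk marks a camera adjusted p under 0.05 at the preset correlation and a double asterisk a call that also held with an estimated correlation. The ERK list alone has double asterisks, in both comparisons of inhibitor-treated with untreated bone cells.

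Bone cells at passage 9 were set against fat pad cells at passage 3 to see how far they still differed. Lower in bone P9 cells were NNMT, a nicotinamide methyltransferase (12.7 ± 5.26 against 50.6 ± 10.7 FPKM, n = 4 and 3, log2 -1.99 ± 0.32, limma adjusted p = 0.00166), the cytokine IL6 (log2 -1.31 ± 0.34), ENPP4 (-1.49 ± 0.21) and the histone genes HIST1H2BK (-1.20 ± 0.25) and HIST1H2BJ (-1.29 ± 0.25). Higher were CDK15 (9.61 ± 3.04 against 3.22 ± 1.84 FPKM, limma adjusted p = 0.00444), EVA1A (log2 1.56 ± 0.29), NFIX (1.26 ± 0.17) and the translation factor EEF2 (283 ± 35.0 against 128 ± 42.4 FPKM). Of 18 hypoxia genes 0 were higher, 8 lower and 10 did not pass (0 and 12 adjusted over the list alone, median log2 -0.47, camera adjusted p = 9.06e-06, or 0.584 with an estimated correlation), among them the collagen hydroxylase subunit P4HA1 (28.6 ± 1.00 against 58.7 ± 6.71 FPKM), NDRG1 (log2 -1.27 ± 0.23) and DDIT4 (-1.07 ± 0.29). Of 32 cell cycle genes 10 were higher, 0 lower and 22 did not pass (12 and 1 adjusted over the list alone, median log2 0.21, camera adjusted p = 0.00117, or 0.633 with an estimated correlation), among them CDT1 (log2 0.79 ± 0.17). Of 34 ribosomal protein genes 3 were higher, 0 lower and 31 did not pass (3 and 0 adjusted over the list alone, median log2 0.26, camera adjusted p = 1.46e-05, or 0.633 with an estimated correlation), among them RPS15 (log2 0.81 ± 0.18). With quantile normalization the cell cycle and ribosomal sets were at camera adjusted p = 0.132 and camera adjusted p = 0.127. EZH2 differed by 0.14 ± 0.10 (limma adjusted p = 0.38).

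Of the 1678 genes that passed, 953 were higher and 725 lower in bone P9 cells, 126 of them by at least 1 in log2(FPKM + 1). After rescaling to TPM 1089 were higher and 356 lower. The count was 497 without MFP P3 replicate 1 and 292 with the 2 groups alone. Of 72 named genes that passed, 36 lost the call when 1 or another library was left out. All 72 lost it with the replicate number as a block, which here groups different mice. Some genes that differed in bone P3 cells still did, CDK15 being higher and ENPP4 lower. Bone P3 and bone P9 cells are here set against the same 3 fat pad libraries, which makes both differences alike. Their covariance was 0.0594, where simulations with no effect and the same sharing gave 0.0271. Their correlation r was 0.536, against 0.551 in those simulations. The simulations drew deviations from all 22 libraries, and the replicates that differed most were of MFP P3. The fat pad libraries could not be halved, so the likeness is not told apart from sharing. Passage differs between these groups, so site and time in culture are not separated.

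The parental cells gave 1 library, which has no replicate check and no test. Against the mean of the 10 passage 3 libraries of the 3 sites, the immediate early EGR1 stood higher (5.43 against 1.12 ± 0.981 FPKM, SD, n = 10), as did MT-ND5 (3439 against 1772 ± 268). Lower in the parental library were INSIG1, a brake on sterol synthesis (7.54 against 29.1 ± 12.9 FPKM), SCD (20.2 against 66.6 ± 31.7), the stress factor DDIT3 (log2 -1.43) and S100A6 (log2 -1.17). In total 2327 genes lay outside the range of the 10 libraries, 17.7% of those tested, where chance gives 18.2%. The median log2 difference of cholesterol synthesis genes from fat pad, lung and bone cells was -0.90, -0.91 and -0.45, at percentile 0 of random lists for each site, which describes these libraries and is no test. The mitochondrial list was at percentile 100 for each site. All genes with symbols starting with MT-, a wider set, took 23.5% of fragments, the most of all 23 libraries.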

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

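Values of chosen genes, most of them named in the text, and the depth, mitochondrial share and GC content of the bone libraries were tested for a single library apart from the others of its group, group by group, with the gap as a share of the range (Dixon's ratio at its published limit for 4 values). Of 231 groups tested 10 passed that limit, where chance flags about 1 in 20 groups, or 11.6. The genes tested were chosen after their changes had been seen. No value was removed.

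In bone P3, SCD stood at 80.7 FPKM in replicate 3 against 27 to 34.5 in the others, PLAT at 30.5 in replicate 3 against 5.03 to 8.78, and EPHA2 at 13 in replicate 2 against 22.2 to 23.1. KLF2 stood at 7.69 in replicate 1 against 1.84 to 2.58, and HLA-DPA1 at 1.5 in replicate 1 against 0.547 to 0.704. LCP1 was at 0.0196 in replicate 2 and 0 in the others. In bone P6, MYC stood at 41.6 in replicate 1 against 60.2 to 61.4, and HMGN5 at 1.24 in replicate 1 against 0.39 to 0.417. In inhibitor-treated cells, ENPP4 stood at 2.09 in replicate 4 against 2.42 to 2.49, and PFKP at 58.7 in replicate 4 against 55.2 to 55.6.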

How the results depend on the processing

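Chosen after the data were seen were the GC and length corrections, voom, the fits without mouse 320, the test within mice and the simulated ranges of covariances under alternatives; the other alternatives were fixed before. Of 11911 alternatives for named genes 9853 gave the same call, 1994 a weaker one, 63 a stronger one and 1 changed sign, genes that never passed included. Of named genes that passed, none kept the call in every alternative in the site comparisons or in bone P9 against MFP P3. There the block on the replicate number, which names different mice, ended every call by itself, so that alternative says little about the genes. The compared groups alone also ended 34 of 36 calls for bone P3 against MFP P3 and 23 of 23 for lung P3 against MFP P3. They ended 15 of 15 for bone P3 against lung P3 and 41 of 72 for bone P9 against MFP P3. Leaving out 1 or another library ended 23, 23, 12 and 36 calls, in the same order. Elsewhere the numbers that kept the call in every alternative were 27 of 86 at passage 6, 51 of 87 at passage 9, 56 of 103 under the inhibitor and 1 of 4 against bone P6. The change of sign is MT-ND3 under the inhibitor with quantile normalization, at log2 0.057 (limma adjusted p = 0.852), a scaling that can hide changes of genes with very high values. Of 254 alternatives for counts and covariances 77 moved.

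Bone P3 against MFP P3 gave 202 genes after rescaling to TPM, 3 with the groups alone, 0 with the replicate block, 615 with GC trend and level removed, 674 with GC trend removed and median-ratio scaling, 0 with GC trend removed and the block, and 144 without mouse 320. Replicate numbers of different sites name different mice, and the limma model without the block gave 2769 genes at an unadjusted p under the threshold. Leaving out 1 library gave 66 to 1048.

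Lung P3 against MFP P3 gave 110 without the filter, 92 with median-ratio scaling, 1 with the groups alone, 0 with the block, 103 with the GC trend removed, 77 with the level also removed, 85 with GC trend removed and median-ratio scaling, and 0 with GC trend removed and the block (limma, 2180 unadjusted without it). Leaving out 1 library gave 2 to 321.

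Bone P3 against lung P3 gave 31 with quantile normalization, 0 with the groups alone, 0 with the block, 33 with length trend and level removed, 34 with length trend removed and median-ratio scaling, 34 with GC trend removed and median-ratio scaling, 4 with GC trend removed and the block, 35 with voom and 6 without mouse 320 (limma, 1472 unadjusted). Leaving out 1 library gave 3 to 27.

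Bone P6 against bone P3 gave 792 without the filter, 2175 after rescaling to TPM, 278 with the groups alone, 2569 with the block, 569 with GC trend and level removed and 603 with GC trend removed and median-ratio scaling (range leaving out 1 library 554 to 1854). Bone P9 against bone P3 gave 1191 without the filter, 1241 with the groups alone, 3180 with the block and 3256 with GC trend removed and the block (range 1283 to 2047). The inhibitor against bone P3 gave 1670 with GC trend and level removed and 1686 with GC trend removed and median-ratio scaling (range 2056 to 2703). The inhibitor against bone P6 gave 2 with a pseudocount of 0.1, 14 without the filter, 3 with the groups alone, 35 with the block, 40 with GC trend removed and the block and 8 with voom (range 1 to 5).

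Bone P9 against MFP P3 gave 292 with the groups alone, 0 with the block and 0 with GC trend removed and the block (limma, 3850 unadjusted without it), with a range of 497 to 2474 leaving out 1 library. Of 60 list calls 2 held with an estimated correlation. At the preset correlation, leaving out 1 library gave 57 to 67 list calls. The split-mouse covariance of the passage 9 and inhibitor changes was 0.0909 with a pseudocount of 0.1, 0.0242 without the filter, 0.0811 after rescaling to TPM and 0.0492 with the GC trend removed, with a range of 0.0598 to 0.0627 leaving out 1 mouse. The covariance of the bone and passage 9 changes ranged over -0.0222 to -0.0121, and that of the bone and inhibitor changes over -0.0201 to -0.00192, the ends of the latter without MFP P3 replicates 1 and 3. With a pseudocount of 0.1 the parental difference was 2.56 for EGR1, 2.38 for SLC16A7, 2.17 for SNX10 and 1.43 for NUP210.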

Other observations

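Genes of other groups also changed under the inhibitor. The growth factor TGFB1 rose from 4.29 ± 0.790 to 11.9 ± 2.43 FPKM (n = 4 and 4, log2 1.28 ± 0.14, limma adjusted p = 1.77e-05), the progenitor factor SOX9 by 1.28 ± 0.15, and VEGFA, which drives vessel growth, by 1.11 ± 0.16 on the log2 scale. The plasminogen activator PLAT rose from 12.9 ± 11.9 to 30.7 ± 6.46 FPKM. Of 13 stemness genes 6 rose, 2 fell and 5 did not pass (6 and 2 adjusted over the list alone, median log2 0.27, camera adjusted p = 0.405, or 0.567 with an estimated correlation), with ABCG2 among the falls and NOTCH1 (log2 0.85 ± 0.19) among the rises. Of 14 epithelial genes 6 rose, 0 fell and 8 did not pass (6 and 0 adjusted over the list alone, median log2 0.27, camera adjusted p = 0.18, or 0.567 with an estimated correlation), among them the junction genes DSP (log2 1.38 ± 0.38) and JUP (1.25 ± 0.19).

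The tests of GC and length trends below were chosen after the result was seen, and their form and reading were settled after first values had been seen. More genes rose than fell in the later bone libraries against bone P3, and of the calls under the inhibitor 89.4% were rises, or 65.4% with median-ratio scaling. With a GC trend removed and each library's level kept, the share was higher at both scalings, 92.0% and 73.8%. It was 69.4% when the level was removed too, so rises outnumbered falls in every form. Keeping the level leaves in place part of what sets the balance of rises and falls, so a GC trend is not excluded. With a length trend removed the share was lower at both scalings, 85.5% and 57.4%, or 51.5% without the level. A length trend, or the deposited scaling with mitochondrial transcripts taking fewer fragments in later libraries, could account for part of the excess and stays open. FOSL1 and TIMP2 rose, and FPR1 and ABCG2 fell, under the inhibitor with every scaling and with both forms of the GC correction.

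The changes of bone cells under the inhibitor and by passage 9 were alike. Shared bone P3 libraries could make them so, but with different mice on each side 74.7% of the covariance remained, above the range of simulations with no effect. Without the filter 67.7% remained (0.0242, simulated up to 0.0132 on the same genes), and with a pseudocount of 0.1 49.98% (0.0909, simulated up to 0.0855). Shared libraries are therefore excluded as the whole cause in the main fit. With a pseudocount of 0.1 the share just misses the bound that was set beforehand for excluding them. No library separates time in culture from the inhibitor, since the labels do not give how long untreated cells were held.

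The passage 6 change might in part be a state of the bone P3 libraries alone. Its covariance with the difference of the other sites from bone P3, with different mice on each side, was 0.0116, or 22.9% of its covariance between mice. Simulations with no effect gave -0.0189 to 0.0299, a range that holds this value, which leaves the question open. The design gives no other group that would separate such a state from time in culture.

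Libraries were regrouped in every way with the same group sizes. The real grouping was the only one, 1 of 35, with as many genes for bone P3 against MFP P3 (385, highest other 154), bone P3 against lung P3 (20, highest other 1) and bone P9 against MFP P3 (1678, highest other 24). For lung P3 against MFP P3 it was 1 of 10 (50, highest other 20), a share that cannot be small with 3 libraries each. The bone groups come from the same 4 mice, so there only the 8 groupings that part the libraries of every mouse were compared. The real one gave the most genes for bone P6 against bone P3 (1428, highest other 0), bone P9 against bone P3 (1938, highest other 2), the inhibitor against bone P3 (2799, highest other 1) and the inhibitor against bone P6 (5, highest other 1). The smallest possible share is 1 in 8, or 12.5%, so these groupings are too few for a share under 0.05. Among all 35 groupings of bone P6 and bone P3 libraries, 1 with 785 genes put bone P3 replicate 1 with bone P6 replicates 1, 2 and 4.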
